A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

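Poly(A)+ RNA was measured in 3 wild type and 3 rad24 deletion libraries of Schizosaccharomyces pombe. Per the labels' protocols, RNA was purified with hot acid phenol from log phase cultures in YES medium at 30 °C, and libraries were made with a stranded mRNA kit and sequenced as pairs of reads. Per the submitters' processing notes, HISAT2 2.1.0, SAMtools, HTSeq 0.10.0 and DESeq2 were used with the genome build ASM294v2. The strand setting of the counting and the versions of SAMtools and DESeq2 are not given in the sources used here. HTSeq leaves out reads that match several places or overlapping features, unless told otherwise, so the levels of near-identical copies and of overlapping genes are uncertain.

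The authors deposited raw counts per gene for each library. The count table had 6987 rows with 1 identifier in 2 rows, of which the first was kept (the other held no count). The authors' deposited table of the comparison holds log2 fold changes with standard errors, p-values, adjusted p-values and a test score, per the file headers. It also holds mean normalized counts, a signal of normalized reads per gene averaged by the authors, per the file headers. Its overall mean lay within 1% of the mean of its group averages for only 336 of 6177 genes with a mean above 10, so how that column was made is open, and it was not used further. Samples were grouped by their genotype labels.

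Genes were tested in edgeR 4.0.16 under R 4.3.3 with limma 3.58.1. Genes below the filterByExpr minimum for the group size were left out (902, of which 359 had no count), leaving 6084. TMM factors were 0.946, 0.928 and 0.959 in wild type and 1.049, 1.054 and 1.074 in the mutant. The quasi-likelihood test was run with genotype as the only term, and p-values were adjusted over the tested genes by the Benjamini-Hochberg method at a threshold of 0.05, with a bound of 2-fold where stated. CPM were computed with the TMM-scaled library sizes, and every fold change is the mutant over wild type. Each SE of a log2 fold change was derived from the test, as its absolute value divided by the square root of the F statistic. Each SE printed below is smaller than the one in the authors' deposited table, such as 0.05 against 0.13 for tgp1 and 0.10 against 0.48 for map2. These SEs may therefore overstate the precision. All SDs and means are over n = 3 libraries. Non-coding RNA genes were taken by the gene type in the authors' deposited table, and identifiers were not used for this. Intervals and floors cover counting error only, since the labels name no molecular identifiers.

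The genes named in the text were chosen by a rule written before the data were examined. It takes rad24, rad25, pho1, pho84, tgp1 and their upstream lncRNAs. It adds the 12 protein-coding and 4 non-coding genes with the largest rise and the largest fall among those called, with all 3 mutant libraries on one side of all 3 wild type libraries and a mean of at least 5 CPM in the higher group. It further adds up to 4 members of each list with the largest change past the threshold. Other genes in the text (tdh1, ste11, fbp1 and the other phosphate genes) were chosen after their values were seen. The 32 gene lists were fixed in advance, and of their names 690 were matched by name, 9 by an older name and 5 by a name in the reference annotation, while 17 were not matched. In the ribosomal protein list, given as a name pattern, 3 matches were subunits of RNase P or MRP and were left out after their names were seen. Some names matched a gene of another function than the list (car1, an arginase gene, in the thiamine list, cdc20 of DNA polymerase in mitosis, clp1, a phosphatase gene, in 3′ processing, gap1, a GTPase activator gene, in nitrogen starvation, pwp1 in cell wall and sdh4 in respiration). They were kept in the counts and left out in an alternative added after the data were seen. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 32 lists. The result of 1 called list is not reported here.

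The steps were tested on simulated counts for 6059 genes drawn from the means and totals of these libraries, with known changes added. Of the simulated changes of 1.25-fold, 1.5-fold, 2-fold and 4-fold, 89.8%, 94%, 98% and 100% were recovered, and 10 unchanged genes were called. At each size at most 50 genes were changed, with rises and falls drawn in equal number. Most genes differ in the real data, and how the scaling behaves in that case was not tested. Counts of libraries of the same group differed by more than sampling noise (chi-square per degree of freedom 2.44 to 7.94), so no library was taken as deposited 2 times.

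Alternatives were RLE and upper quartile factors, library size only, no filter, a stricter filter of 50 counts in every library of a genotype, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block, each library left out in turn, protein-coding genes only, a test against a 1.5-fold change and, added after the data were seen, libraries thinned to the smallest total. The reference annotation at hand is of ASM294v3 and not of the build used by the authors, so no coordinates are given. It was used for names and for which genes neighbour or overlap each other, and 6833 identifiers matched. Copies of genes were sought with BLAST 2.17.0 in the ASM294v3 sequence. Permutation and Fisher's exact tests were run in SciPy 1.17.1 under Python 3.11.15, and figures were drawn with matplotlib 3.10.9.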

Results

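Poly(A)+ RNA of the fission yeast Schizosaccharomyces pombe was sequenced in 3 libraries of a wild type h+ strain and 3 libraries of an h+ strain in which rad24 had been replaced by a drug marker. Both strains were grown to log phase in the rich medium YES at 30 °C. Total counts were 15282140, 11539278 and 14560026 in the wild type libraries and 21730112, 19396868 and 20000648 in the mutant libraries, so each mutant library was deeper than each wild type library. The labels call the libraries of a group replicate experiments and do not say that they came from separate cultures, so the p-values measure only the spread between these libraries. Pearson correlations of log CPM were 0.9956 to 0.998 within a group and 0.938 to 0.945 between the groups, and the first principal component carried 93.5% of the variance. The comparison asks what loss of Rad24, a 14-3-3 protein that binds phosphorylated partners, does to the transcriptome, with attention to genes repressed by transcription of an upstream long non-coding RNA.

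The deleted gene was checked first. The wild type libraries held 22565, 18442 and 21135 counts of rad24 (SPAC8E11.02c), and the mutant libraries held 27, 39 and 15. The mean level was 1599 ± 109 CPM in wild type and 1.26 ± 0.609 CPM in the mutant (SD, n = 3 each), a log2 fold change of -10.31 (SE 0.13, edgeR adjusted p = 1.07e-15). By this gene each of the 6 libraries had the genotype its label gives. The other 14-3-3 gene, rad25 (SPAC17A2.13c), rose from 608 ± 19.1 to 846 ± 12.1 CPM (log2 fold change 0.48, SE 0.04, edgeR adjusted p = 1.08e-07).

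The phosphate genes under lncRNA control were higher in the mutant. The acid phosphatase gene pho1 (SPBP4G3.02) rose 10.4-fold, from 904 ± 50.9 to 9385 ± 212 CPM (SD, n = 3 each; log2 fold change 3.38, SE 0.06, edgeR adjusted p = 1.62e-14). The glycerophosphodiester transporter gene tgp1 (SPBC1271.09) rose 25.3-fold, from 11.7 ± 0.693 to 296 ± 12.6 CPM (log2 fold change 4.66, SE 0.05, adjusted p = 7.42e-16). The phosphate transporter gene pho84 (SPBC8E4.01c) rose 1.64-fold, from 1581 ± 110.1 to 2585 ± 51.5 CPM (log2 fold change 0.71, SE 0.05, adjusted p = 3.77e-08). In the mutant, pho1 took 0.961%, 1.01% and 1.01% of the counts of the libraries, against 0.091%, 0.0811% and 0.0839% in wild type. The upstream lncRNAs of these 3 genes are not rows of the count table and were not analysed here. In the ASM294v3 annotation each overlaps its gene on the same strand, so reads of the lncRNA and of the mRNA are not separated in the values above.

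**Figure D1:**
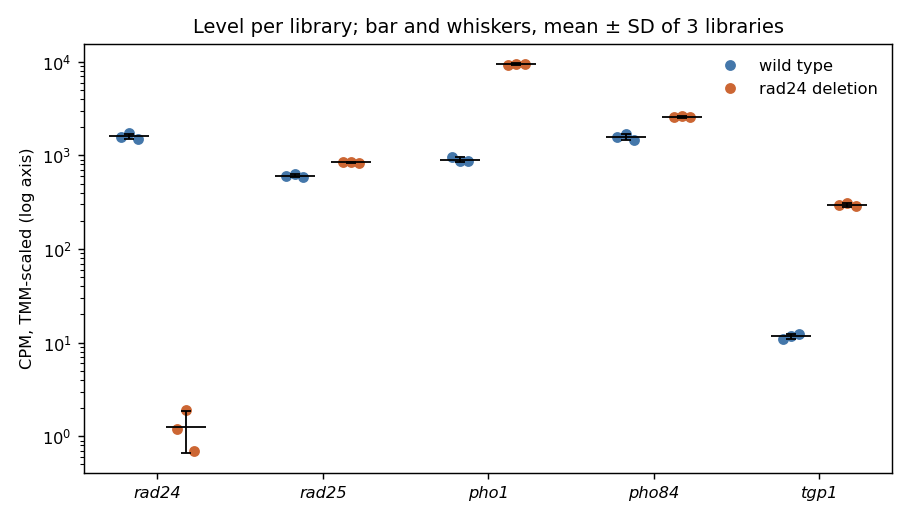
Level of rad24, rad25, pho1, pho84 and tgp1 in each library, in TMM-scaled CPM on a log axis, with a point per library and the mean ± SD of the 3 libraries of each group. The mutant points of pho1 lie between 9160 and 9580 CPM and those of wild type between 874 and 962 CPM.

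The change was not shared by the phosphate list as a whole. Of its 8 tested members 4 were higher and 3 lower at an adjusted p below 0.05. The transporter gene SPAC23D3.12 fell by 1.05 on the log2 scale, the vacuolar polyphosphate gene vtc4 by 0.46 and the phosphodiesterase gene gde1 by 0.28. The phosphatase gene pho8 rose by 0.32, and pho7, which encodes the transcription factor of the regulon, had a log2 fold change of 0.00 (adjusted p = 0.995). The median of the list was 0.16 and its mean 0.91. The camera test called it higher (adjusted p = 0.00422), with adjusted p = 0.287 with an estimated correlation and adjusted p = 0.636 with limma-voom.

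Across the genome, 4766 of 6084 tested genes differed between the genotypes at an edgeR adjusted p below 0.05, 2491 higher and 2275 lower in the mutant. Of these, 776 changed at least 2-fold, 440 higher and 336 lower. Higher genes made up 52.3% of the calls with TMM scaling and 67.0% with scaling by library size only, where the median log2 fold change of all genes moved from 0.02 to 0.19. Upper quartile factors gave 61.1% and a median of 0.12. Among 4985 protein-coding genes 4054 were called, and 468 of them changed at least 2-fold, 261 higher and 207 lower. The common dispersion was a biological coefficient of variation of 3.61%, so small differences passed the test.

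**Figure D2:**
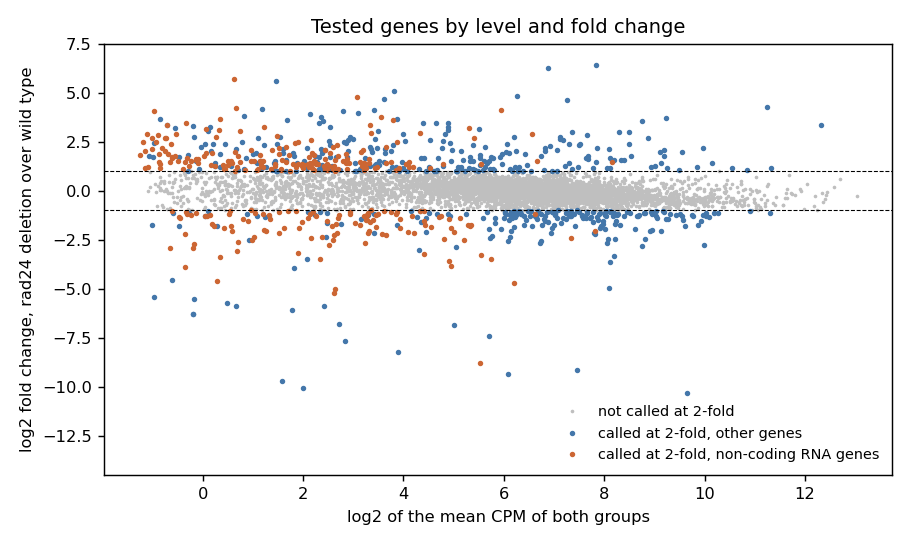
Each point is 1 of the 6084 tested genes, with the log2 of the mean CPM of both groups on the horizontal axis and the log2 fold change of the mutant over wild type on the vertical axis, and dashed lines at 2-fold. Genes called at 2-fold are coloured, 440 of them above and 336 below 0.

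Under the rule for named genes, the largest rise of a protein-coding gene was that of the P-factor pheromone gene map2. It rose 87.6-fold, from 5.14 ± 0.0173 to 450.3 ± 50.4 CPM (log2 fold change 6.45, SE 0.10, edgeR adjusted p = 8.94e-15). The adducin gene mug14 rose 76.8-fold to 232 ± 14.4 CPM, and the gene of the RNA-binding protein Mde7 rose 49.6-fold from 0.10 ± 0.104 to 5.42 ± 0.914 CPM. The zinc finger gene hpz2 rose 33.9-fold, the predicted 3-hydroxyacyl-CoA dehydrogenase gene SPAC4H3.08 28.5-fold and mug108 25.4-fold. The glyceraldehyde 3-phosphate dehydrogenase gene gpd3 rose 19.3-fold, from 239 ± 33.1 to 4622 ± 562 CPM, while its paralog tdh1 had a log2 fold change of -0.14 (adjusted p = 0.0707). The short chain dehydrogenase gene SPCC1739.08c rose 17.4-fold, the DNA polymerase gene pol4 16.9-fold, the sporulation septin gene spn6 15.7-fold and the transcription factor gene atf21 15.4-fold. With tgp1, these are the 12 largest rises among the protein-coding genes that the rule admits, and genes outside it were not ranked. The edgeR adjusted p-values among them ran from 7.42e-16 to 1.95e-08.

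Under the same rule the largest falls of protein-coding genes, after rad24 itself, were at the ends of chromosomes I and II. No count of ftm4, a member of a subtelomeric membrane protein family, or of SPAC186.06, a PhzF family gene, was found in the mutant, where a floor of 3 counts over the group gives levels at least 167-fold and 130-fold lower than in wild type. Reads of ftm4 can be shared with near-identical copies. SPAC977.18 fell from 136 ± 29.9 to 0.206 ± 0.151 CPM (log2 fold change -9.35, SE 0.30, edgeR adjusted p = 4.62e-12). The aldo/keto reductase gene SPAC750.01 fell from 352 ± 20.3 to 0.615 ± 0.119 CPM (log2 fold change -9.14). The Golgi calcium and manganese antiporter gene gdt1 fell from 103 ± 0.837 to 0.590 ± 0.361 CPM (log2 fold change -7.41). The log2 fold changes were -8.22 for SPBPB2B2.18, -7.67 for ftm2, -6.82 for the pyruvate decarboxylase gene pdc102, -6.10 for the amide hydrolase gene fah1 and -5.90 for the transcription factor gene grt1. The proteasome regulator gene fub2, which follows pho1 on the same strand in the ASM294v3 annotation, fell from 63.8 ± 12.8 to 0.540 ± 0.0438 CPM (log2 fold change -6.85, SE 0.22, adjusted p = 5.64e-12).

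Non-coding RNA genes were called less often than protein-coding genes, and their changes were more often large. Of 1034 tested, 676 were called, 395 higher and 281 lower (65.4%, against 81.3% of protein-coding genes; Fisher's exact test, two-sided, odds ratio 0.434, p = 1.62e-27). At least 2-fold changes were found in 293, 174 higher and 119 lower (28.3% against 9.39%; Fisher's exact test, two-sided, odds ratio 3.82, p = 3.32e-52). Both tests take genes as independent and did not match them by level. A difference in level between the classes was therefore not separated from a difference of class. Among 587 antisense RNA genes 76 rose and 81 fell at least 2-fold, and among 360 intergenic RNA genes 84 rose and 30 fell. Among the non-coding genes that the rule for named genes admits, the largest rises were in meu3 (log2 fold change 4.78), brl1-antisense-1 (4.10), meu19 (3.79) and lid2-antisense-1 (3.62). The largest falls among them were in prl61 (-8.79), grt1-antisense-1 (-5.24), isp3-antisense-1 (-5.04) and cbp6-antisense-1 (-4.71). The strand setting of the counting is not given in the sources used here, so reads of an antisense RNA and of the gene opposite are not known to have been told apart.

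Of 32 gene lists fixed before the data were examined, the camera test with a preset correlation called 16, 10 higher and 6 lower in the mutant. None was called with an estimated correlation, where 4 lists had an unadjusted p below 0.05. The directional fry test, which does not compare a list with other genes, called 27. Adjusted over the list alone, the numbers of higher and lower members equalled those given below over all genes, except in the meiotic list.

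Genes of mating and meiosis were higher. In the list of P-cell genes, which h+ cells express, map2, the M-factor receptor gene map3 (log2 fold change 2.76) and the regulator gene map1 (1.07) rose, and the protease gene sxa1 fell by 0.77 on the log2 scale. This list of 4 tested members was called (camera adjusted p = 0.000111), with adjusted p = 0.287 with an estimated correlation and adjusted p = 0.174 with limma-voom. Of 20 genes of the Ste11 and pheromone response list 16 rose and 2 fell (camera adjusted p = 2.89e-07, and adjusted p = 0.287 with an estimated correlation). They included mei2, the gene of an RNA-binding regulator of meiosis, from 78.9 ± 6.58 to 642 ± 3.67 CPM (log2 fold change 3.02), the G-protein regulator gene rgs1 (3.02), the Ras exchange factor gene ste6 (1.92) and the MAP kinase gene spk1 (1.70). The mRNA of ste11 itself had a log2 fold change of -0.01 (adjusted p = 0.709).

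Of 19 meiotic transcripts that the RNA-binding protein Mmi1 marks for removal in growing cells, 13 rose and 1 fell, or 13 and 0 adjusted over the list alone. Examples were meu31 (2.67), meu32 (2.20), mug4 (2.05) and rec25 (1.94). The list was called (camera adjusted p = 0.0214), with adjusted p = 0.372 with an estimated correlation and 0.0524 with scaling by library size only. Of 17 spore and late meiosis genes 13 rose and 3 fell (camera adjusted p = 0.0307, and adjusted p = 0.372 with an estimated correlation). The spore wall gene isp3 rose from 19.0 ± 0.683 to 128 ± 37.2 CPM (log2 fold change 2.75). The low-level genes spo4 (3.66), mfr1 (2.25) and meu14 (2.15) rose to 1.05 ± 0.108, 1.62 ± 0.501 and 8.41 ± 1.48 CPM.

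**Figure D3:**
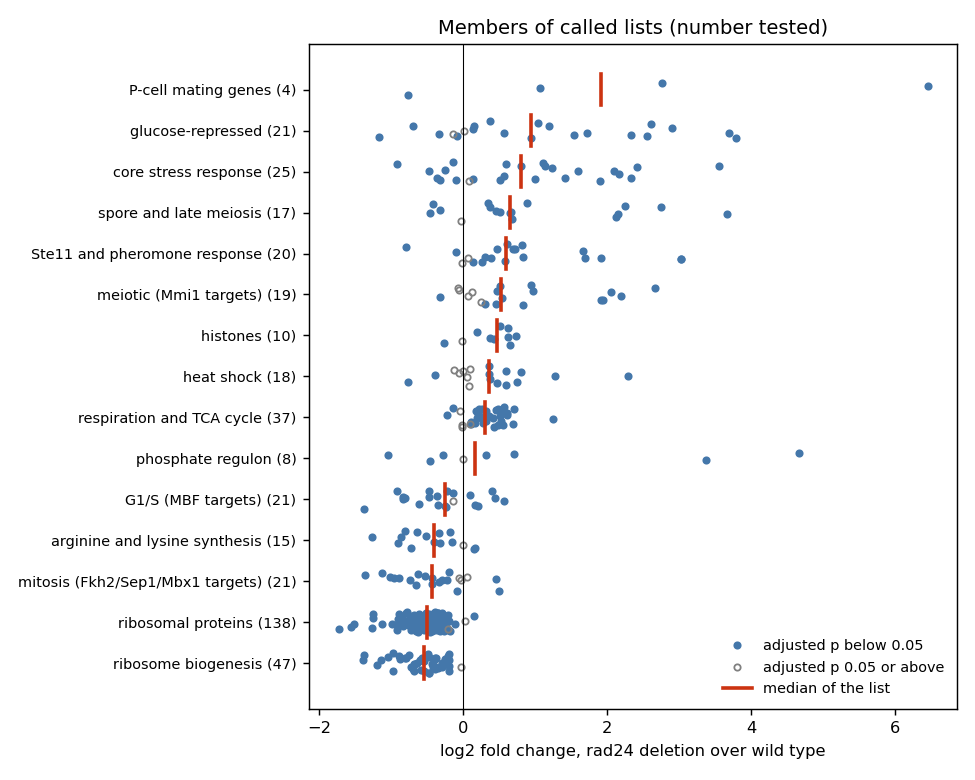
Log2 fold change of each tested member of 15 of the 16 called lists, with filled points at an adjusted p below 0.05, open points above it and a red bar at the median of the list; the number of tested members stands in parentheses. Medians run from -0.54 for ribosome biogenesis genes to 1.92 for P-cell genes, and single members lie on the other side of 0 in most lists.

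Of 25 core stress genes 17 rose and 7 fell (median 0.80, camera adjusted p = 7.83e-06, and adjusted p = 0.287 with an estimated correlation). The ferritin-related gene rds1 rose from 67.5 ± 2.80 to 793 ± 63.8 CPM (log2 fold change 3.55), and the small heat shock gene hsp16 (2.41), the hexitol dehydrogenase gene tms1 (2.33) and sro1 (2.16) rose with it. Of 18 heat shock genes 10 rose and 2 fell (median 0.36, camera adjusted p = 0.0116, and adjusted p = 0.49 with an estimated correlation). The chaperone genes ssa1 (2.29), hsp104 (1.27) and psi1 (0.80) rose, and the mitochondrial mge1 fell by 0.77 on the log2 scale. Of 21 glucose-repressed genes 15 rose and 4 fell (median 0.94, camera adjusted p = 9.96e-06, and adjusted p = 0.287 with an estimated correlation). The hexose and gluconate carriers ght6 (3.79), ght3 (3.69) and ght5 (2.61) and the invertase gene inv1 (2.90) were among those that rose, while the gluconeogenesis gene fbp1 fell by 0.70. Of 37 respiration and TCA cycle genes 31 rose and 2 fell (median 0.31, camera adjusted p = 0.000487, and adjusted p = 0.336 with an estimated correlation), led by the citrate synthase gene cit1 (1.24), cox8 (0.70), idh2 (0.69) and cox12 (0.61). Of 10 histone genes 8 rose and 1 fell (median 0.47, camera adjusted p = 0.0417, and adjusted p = 0.49 with an estimated correlation), including hhf1 (0.73), hht1 (0.65), hhf2 (0.63) and hta2 (0.62). The histone call was lost without wild type replicate 1 (adjusted p = 0.0706), without mutant replicate 2 (0.0658) and with protein-coding genes only (0.0512). Some histone genes are near-identical copies that can share reads, which was not measured here.

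Ribosome genes moved down together by a modest amount. Of 138 ribosomal protein genes 135 fell and 1 rose, with a median log2 fold change of -0.50 (camera adjusted p = 2.75e-09, and adjusted p = 0.49 with an estimated correlation). The largest falls were in rpl1602 (-1.73), rps001 (-1.55), rpl1603 (-1.52) and rps2602 (-1.27), each with a paralog that can share its reads. Of 47 ribosome biogenesis genes 46 fell and none rose (median -0.54, camera adjusted p = 2.75e-09, and adjusted p = 0.49 with an estimated correlation), among them arx1 (-1.40), rpf2 (-1.38), tsr2 (-1.20) and erb1 (-1.15). With scaling by library size only the medians of both lists were -0.33 and -0.38, where the median of all genes was 0.19.

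Genes of cell division fell in the mutant. Of 21 mitosis genes 16 fell and 2 rose (median -0.43, camera adjusted p = 0.00184, and adjusted p = 0.287 with an estimated correlation), with chs2 (-1.36), myp2 (-1.12), imp2 (-1.02) and mob1 (-0.96) as the largest changes. Of 21 G1/S genes 14 fell and 6 rose (median -0.25, camera adjusted p = 0.0385, and adjusted p = 0.49 with an estimated correlation), including the mitotic inhibitor kinase gene mik1 (-1.38), rad21 (-0.92), suc22 (-0.83) and cdt1 (-0.83). The G1/S call was lost with upper quartile factors (adjusted p = 0.0585), with library size only (0.104) and with protein-coding genes only (0.0512). Of 15 genes of arginine and lysine synthesis 12 fell and 2 rose (median -0.41, camera adjusted p = 0.00432, and adjusted p = 0.289 with an estimated correlation), among them lys12 (-1.26), arg4 (-0.90), arg1 (-0.86) and arg12 (-0.81).

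The other 16 lists were not called by the camera test, and members moved both ways in each. Of 6 tested M-cell genes, markers of the other mating type, 4 rose and 2 fell (camera adjusted p = 0.943). The M-factor genes mfm2 (2.42), mfm1 (2.38) and mfm3 (0.70) rose from low levels and the P-factor receptor gene mam2 fell by 3.04. The call of mfm3 was lost without wild type replicate 2 (log2 fold change 0.77), without wild type replicate 3 (0.39), without mutant replicate 1 (0.66) and without mutant replicate 2 (0.64). Of 17 nitrogen starvation genes 5 rose and 9 fell (camera adjusted p = 0.696), with isp4 (2.12) and per1 (1.51) up and the ammonium transporter gene amt2 (-1.19) down. Of 13 iron genes 7 rose and 5 fell (camera adjusted p = 0.195). The iron uptake genes fio1 (2.54), str1 (2.42) and fip1 (2.41) rose, as did srx1 (1.48), which also stands in the list of Pap1 targets. Of 14 such oxidative stress genes 5 rose and 6 fell (camera adjusted p = 0.943), with the catalase gene ctt1 (1.41) and trx1 (1.17) up and the efflux gene bfr1 (-0.92) down.

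In the copper and zinc list 3 of 11 genes rose and 7 fell (camera adjusted p = 0.129), with zym1 (1.91) up and adh4 (-2.14), ctr4 (-1.07) and zrt1 (-0.93) down. In the thiamine list 3 of 11 rose and 4 fell (0.943), with snz1 (-1.25), thi9 (-1.09) and tnr3 (-0.71) down. Its largest rise, car1 (1.69), is that of an arginase gene matched by name alone, without which 2 of 10 rose and 4 fell (adjusted p = 0.456, median -0.03). In the sterol list 8 of 20 rose and 10 fell (0.435), with ole1 (1.15) and sre1 (0.92) up and the squalene monooxygenase gene erg1 (-1.79) and erg31 (-0.96) down. In glycolysis 4 of 13 rose and 2 fell (0.264), with gpd3 (4.27), adh1 (0.59), pdc201 (0.56) and pgi1 (0.34) up. In the cell wall list 5 of 18 rose and 10 fell (0.109), with bgl2 (1.23) up and omh1 (-2.05), bgs3 (-1.10) and bgs1 (-1.05) down. Of 16 flocculins and adhesins 6 rose and 8 fell (0.731), with the mating adhesins map4 (2.83) and mam3 (0.72) and gsf2 (0.56) up and pfl7 (-3.47) down. In the methionine list 3 of 15 rose and 7 fell (0.225), with sua1 (0.76) up and met9 (-1.01), met11 (-0.72) and met6 (-0.70) down.

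Of 29 genes of 3′ processing and termination 3 rose and 14 fell (camera adjusted p = 0.22, and adjusted p = 0.03 with limma-voom), and none changed 2-fold. The largest changes there were in csk1 (-0.70), rhn1 (-0.61), seb1 (-0.56) and cdk9 (-0.44). Of 26 RNA surveillance genes 9 rose and 11 fell (camera adjusted p = 0.7), with mtr4 (-0.96), mmi1 (-0.64) and rrp41 (-0.42) down and red5 (0.39) up. Of 22 RNAi and heterochromatin genes 12 rose and 5 fell (0.943), with arb2 (0.93) and stc1 (0.73) up and epe1 (-0.97) and chp1 (-0.79) down. Of 21 DNA damage checkpoint genes 8 rose and 9 fell (0.897), with rad54 (0.81) up and mik1, rad3 (-0.76) and rad26 (-0.73) down. Of 3 tested Tf2 retrotransposons, which share reads among copies, Tf2-10 (0.72) and Tf2-2 (0.60) were higher and Tf2-11 (-0.96) lower (0.943). The call of Tf2-2 was lost without wild type replicates 2 (log2 fold change 0.52) and 3 (0.57), and without mutant replicates 1 (0.44) and 3 (0.59).

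The camera direction and the median differed in M-cell genes (median 0.54, camera down), nitrogen starvation (-0.15, up), flocculins (-0.19, up), Pap1 targets (-0.01, up) and thiamine genes (0.04, down). With scaling by library size only, the medians of the lists for 3′ processing (0.08), DNA damage (0.12), RNA surveillance (0.12), methionine (0.09), sterol (0.09), Pap1 targets (0.15) and nitrogen starvation (0.01) lay above 0, against -0.08, -0.05, -0.04, -0.07, -0.07, -0.01 and -0.15 as reported. With upper quartile factors all of them except nitrogen starvation (-0.05) lay above 0 as well. The numbers called turned too: with library size only, 10 genes rose and 7 fell in 3′ processing, and 14 rose and 6 fell in RNA surveillance. They were 11 and 4 in DNA damage, 7 and 6 in methionine and 10 and 8 in sterol. Pap1 targets gave 7 and 6, and nitrogen starvation 8 and 5.

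The authors' deposited table of the same comparison listed an adjusted p for 6689 genes, with 2004 higher and 1941 lower at an adjusted p below 0.05. Of the genes called in the authors' deposited table, 3884 were called here in the same direction, none in the opposite direction, and 61 were not tested here. A further 882 genes were called here and not in the authors' deposited table. Of the 776 genes changed at least 2-fold here, 759 were also changed at least 2-fold in the same direction in the authors' deposited table. The authors' deposited table gave log2 fold changes of 3.38 for pho1, 4.66 for tgp1 and 0.71 for pho84. The authors' deposited table describes the same comparison and was not taken as an independent measurement. Which libraries entered the fit behind the authors' deposited table is not shown, and why the calls differ was not tested.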

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

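The test against a 1.5-fold change and the other settings below were planned, except the thinned libraries and the lists without members of another function, which were added after the data were seen. The number of genes called was 4766 as reported, 4057 when protein-coding genes alone were tested, and between 4488 (DESeq2) and 4874 (library size only) in the other settings that count it. The number changed at least 2-fold was 776 as reported, 464 when protein-coding genes alone were tested, which tests fewer genes, and 1241 in the test against a 1.5-fold change, a lower bound. The count of called lists was 16 as reported, 0 with an estimated correlation and 27 with the directional fry test, which asks another question. Leaving out each library in turn gave 4547 to 4727 genes, 769 to 834 genes at 2-fold, 625 to 668 non-coding genes and 15 to 16 lists, with log2 fold changes of 3.35 to 3.42 for pho1, 0.66 to 0.76 for pho84 and 4.61 to 4.70 for tgp1. Over all settings these 3 genes stayed at 3.35 to 3.54, 0.66 to 0.88 and 4.61 to 4.82, past the threshold in each. With an estimated correlation the adjusted p was 0.287 for the phosphate, P-cell, Ste11, core stress, glucose-repressed and mitosis lists, 0.289 for arginine and lysine, 0.336 for respiration, 0.372 for the Mmi1 and spore lists and 0.49 for heat shock, ribosomal proteins, ribosome biogenesis, G1/S and histones. Upper quartile factors ended the call of G1/S (0.0585), library size only that of G1/S (0.104) and Mmi1 targets (0.0524), limma-voom that of the phosphate (0.636) and P-cell lists (0.174), and protein-coding genes only those of G1/S and histones (0.0512 each), while limma-voom added 3′ processing (0.03). Leaving out each library in turn gave an adjusted p of 0.0144 to 0.0706 for histones. The cause was not tested in these cases. Of the other genes named by the rule, none turned direction. Only mfm3 and Tf2-2, at 1 to 3 CPM, lost calls, in 11 results in all, including DESeq2 (log2 fold changes 0.68 and 0.58). Genes named outside the rule were not followed over the settings. With every library thinned to the smallest library total 4561 genes were called, 4513 of them among those reported, with 738 at 2-fold (705 shared) and 593 non-coding genes (579 shared). Without members of another function 16 lists were called, the same as reported. The replicate numbers do not pair the libraries (correlations of deviations -0.001, -0.003 and 0.05, and not every library correlated best with its own number), and with the replicate number as a block 4753 genes, 771 at 2-fold, 671 non-coding genes and 16 lists were called.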

Other observations

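Every test in this part was chosen after the values were seen, except the search for near-identical copies and the test of upstream lncRNAs, and the gene families were also picked after their values were seen. Of 118 tested genes named mug, meu or mde, prefixes given to genes of meiosis, 35 were at least 2-fold higher in the mutant (29.7%, against 4.64% of 4867 other protein-coding genes; odds ratio 8.66, Fisher's exact test, two-sided, p = 3.91e-18, adjusted over 6 family tests 2.35e-17, which does not cover the choice of the families). Falls of 2-fold were found in 4 of them, including mug133 (-2.85) and meu27 (-1.59). The smaller families below were picked for their changes, so only their counts are given. Of 6 tested UPF0300 genes, to which mug133 and meu27 belong, 3 fell and 2 rose, with SPCC737.04 (-3.65) as the largest fall and mug131 (1.09) and SPAC10F6.15 (0.71) higher. Of 3 But2 family genes 3 rose, SPAC27D7.09c (3.49), SPAC27D7.11c (1.99) and but2 (0.33). Of 20 wtf elements tested as protein-coding genes, a family of meiotic drivers whose copies share reads, 18 rose and 1 fell, with a median log2 fold change of 0.97, led by wtf20 (3.04), wtf16 (2.14) and wtf11 (1.67). Of 8 hexose carriers of the ght family 6 rose and 2 fell. These carriers are also members of the glucose-repressed list, and beside those already named ght1 (1.72) and ght4 (1.54) rose, ght7 fell by 1.16, and the most abundant carrier, ght8, had a log2 fold change of 0.15 (1373 ± 85.4 to 1528 ± 12.1 CPM).

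Some neighbours of the phosphate genes and of rad24 differed as well, but so did 78.3% of all tested genes. These neighbours were picked after their values were seen, and whether neighbours change more often than other genes was not tested. At tgp1, the opposite-strand SPNCRNA.1343 fell by 1.30 on the log2 scale and the neighbouring SPBC1271.10c by 1.20. Next to pho84, ecl3, an extender of chronological lifespan, rose from 4.99 ± 0.724 to 53.9 ± 0.892 CPM (log2 fold change 3.44). Next to rad24 in the ASM294v3 annotation, the meiotic recombinase gene dmc1 (2.38), dmc1-antisense-1 (1.54) and suc2 (0.70) were higher. Of 38 tested snoRNA genes 3 rose and 18 fell, so 55.3% were called, a smaller share than among all tested genes. How well libraries of poly(A)+ RNA show the levels of snoRNAs was not tested.

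The 3 libraries of each group make 10 splits of the 6 libraries, too few for a share under 0.05. For genes, genes changed 2-fold and non-coding genes, 1 of the 10 splits, the real one, gave as many calls (4766, 776 and 676), and the highest of the other splits gave 0 in each. In those 9 splits edgeR found at most 8 genes at an unadjusted p below 0.05 and limma-voom called 0. Each of those splits puts both genotypes in both groups, so the genotype difference widens the spread within the groups. Their low gene counts follow from this design and do not show what chance alone would give. For the gene lists, 1 of the 10 splits gave as many as the real 16, and the highest other gave 13. With 3 libraries per group, those splits cannot hold equal shares of both genotypes, so part of the genotype difference remains in them. Their list counts therefore do not show what chance alone would give either.

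In a run at the right end of chromosome I, from SPAC186.04c outward, each of the 10 genes with at least 30 wild type counts kept in the mutant at most 1.5% of its wild type level, while the next gene inward, pfl9, kept 87.3%. Reads shared with near-identical copies do not account for it, since only 2 of the 10 have another copy at 95% identity over 50% of their length. Lower expression at chromosome ends stays open. At the other ends of chromosomes I and II, 12 of 61 such genes among the outermost 40 kept under 5%. The ends were not alike in this: 4 of 19 did at I left, 6 of 20 at II left and 2 of 22 at II right. At this end 10 of 23 did, a larger share than at each other end. The median log2 fold changes of the ends were -0.90, -0.74, -1.85 and -0.48 (I left, I right, II left, II right). Of the 26 genes under 5% in the genome, 22 lie at these ends. Missing DNA at this end in the mutant strain may be the source. The share left of the deleted rad24 was 0.0788%. In an exact Poisson test against that share, 5 of the 10 genes kept more counts at an adjusted p below 0.05. They included gdt1 with 39 counts against 5.27 (adjusted p = 4.14e-20) and SPAC750.01 with 40 against 17.9 (adjusted p = 2.1e-05). Counts spread widely between the mutant libraries, with 22, 5 and 12 for gdt1 and 27, 39 and 15 for rad24. The Poisson test covers counting error only and takes the rad24 share as exact. Carry-over from other libraries in the sequencing pool was not measured, so missing DNA and lower expression cannot be told apart.

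P-cell and pheromone genes were higher in the mutant. If the wild type libraries had come from M cells, M-cell genes would be lower in the mutant, but 4 of 6 were higher. Of these, mfm2 rose from 2.28 ± 0.185 to 12.2 ± 1.18 CPM, while mfm3 lost its call with DESeq2 and without some libraries. The gene sxa1 of the P-cell list was lower, from 1424 ± 41.0 to 836 ± 9.0 CPM. M cells in wild type would not give this if only P cells expressed sxa1, which was not tested here. The M-cell gene mam2, from 35.5 ± 3.06 to 4.31 ± 0.307 CPM, went the other way. Both strains are given as h+, and the mating type of the cells was not measured otherwise. These genes differed between the genotypes, and that loss of rad24 is the cause remains a hypothesis.

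Ribosome genes were lower and core stress and glucose-repressed genes higher. Glucose exhausted at harvest would raise fbp1, which instead had a log2 fold change of -0.70. That is 1 gene, chosen after its value was seen. In the glucose-repressed list 15 of 21 genes rose and 4 fell, with inv1 (2.90) and ght5 (2.61) among the higher. A shortage of glucose therefore stays open. Slower growth or a later harvest of the mutant cultures may give the ribosomal protein median of -0.50, and cannot be told apart from a direct effect of the genotype, because the labels give no growth rate or density.

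As a hypothesis, antisense RNAs may change against their sense mRNAs. Over 425 pairs named by gene, Spearman's rho across genes was -0.10 (permutation p = 0.049, adjusted over 2 relations 0.049) and Pearson's r was 0.00 (permutation p = 0.98), and of 20 pairs in which both changed 2-fold 11 went opposite ways, so the test left it open. Single pairs stood out, such as isp3 (2.75) with isp3-antisense-1 (-5.04) and brl1 (-1.07) with brl1-antisense-1 (4.10). The idea that an upstream lncRNA on the same strand falls where its mRNA rises was not borne out over 270 annotated pairs. These pairs overlap or lie within 500 bases. The lncRNAs of pho1, pho84 and tgp1 are not rows of the count table and so were not among them. There rho was 0.13 (permutation p = 0.032, adjusted 0.049) and r 0.14 (p = 0.018), the opposite sign, and of 11 pairs in which both changed 2-fold 10 went the same way. Genes are not independent replicates, and neighbouring features can share reads, so these values do not decide on lncRNA interference at the phosphate genes.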
